A study of Mus musculus with 25 samples.

How the data were processed

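RNA sequencing of gastrocnemius muscle was available for 25 mice in 5 groups of 5: wild-type mice on vehicle, and mice of a Pompe strain, deficient in acid alpha-glucosidase (Gaa), on vehicle, on enzyme replacement therapy (ERT), on substrate reduction therapy (SRT) or on both (combination). Per the labels, ERT was alglucosidase alfa at 20 mg per kg every other week, SRT was a small molecule given in chow, and treatment lasted 12 weeks. The labels give each library its own animal number, so replicates are separate animals. Groups and replicate numbers were taken from the labels. RNA was extracted with a column kit and made into stranded mRNA libraries, per the labels.

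The deposited values are of 2 kinds, over 17466 genes. The first table holds estimated counts per gene, not normalized. The deposited estimated counts need not be whole (75.2% were not). Their totals ran from 29669030 to 41296194 per library. Kallisto, edgeR and limma are named in the submitters' processing notes without versions or roles. The same notes name the human build GRCh38, while the gene identifiers are those of mouse genes, so no build is assumed for the counting. The second table holds log2 normalized CPM, the counts scaled to a common library size, per the file headers. Tested on the file, each deposited log2 CPM column is a library's own log2 CPM multiplied by a fixed factor between 0.973 and 1.047. The mean factor was 1.018 ± 0.019 (SD, n = 5) in wild-type and 0.998 ± 0.017 (SD, n = 5) in Pompe vehicle libraries. A multiplication of log values compresses or stretches every difference in that library, so this table served only as an alternative. No gene in either table is given by symbol, and 17453 of the 17466 identifiers were matched to symbols in a gene name table. Coordinates are those of the mouse annotation GENCODE M21 on GRCm38.

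Each library's estimated counts were rounded to whole numbers. Genes with too few counts were left out with filterByExpr on the 5 groups, which left 15335 genes holding 99.98% of all counts. Library sizes were scaled by TMM. One coefficient per group was fitted to all 25 libraries with edgeR 4.0.16 in R 4.3.3 (estimateDisp and glmQLFit, robust), and each comparison was tested with the 2-sided quasi-likelihood F test. Benjamini-Hochberg adjustment ran over all genes tested, and genes at an adjusted p under 0.05 were called. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use the TMM-scaled library sizes, and 1 count is worth between 0.0242 and 0.0337 CPM before scaling. A gene without counts in a library can lie anywhere below 3 counts, and folds against a group without counts are lower bounds from that floor per library. Such floors cover counting error only, since the reads carry no molecular identifiers. No 2 replicates were alike within sampling noise: their log2 CPM correlated at 0.961 to 0.986, and the chi-square statistic per gene was at least 19.7.

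The test was tried on simulated counts with every Pompe library at the Pompe vehicle means, with the fitted spread of each gene and each library's size. In the combination group 200 well-counted genes were changed. Genes were drawn independently of each other in a single run, so false calls that come from correlated genes were not measured. For that comparison edgeR recovered 55.2% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 92.4% of those changed 4-fold, with 2.6% of its calls false over 15152 genes. Limma-voom gave 2.7% false calls over the same genes, and DESeq2 gave 12.4% over 15335 genes. Counts by DESeq2 1.42.0 are therefore given as those of another tool with more false calls in this simulation.

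The design, the alternatives, the rule for named genes and 34 gene lists (pathways, fibre types, cell type markers and technical sets) were fixed before the data were examined. The rule takes, in the disease comparison and for each treatment against Pompe vehicle, the 8 called genes with the largest increase and the 6 with the largest decrease whose groups do not overlap, with a mean of at least 1 CPM and a symbol that is not a predicted-gene name. It adds Gaa, Gys1, Gyg, Pygm, Lamp1, Sqstm1, Gpnmb, Cd68 and Myh3, and up to 4 called members of each list that was called or had 2 called members. For other comparisons it takes the 5 called genes with the smallest p in each direction. Genes outside the rule are named as such.

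Gene lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry. The p-values were adjusted over the 34 lists of a comparison. Counts of called members are given over all genes tested and adjusted over the list alone. Other divisions of the same libraries gave about as many lists with the preset correlation (the closing section gives the values), so list calls are printed with the p of the estimated correlation.

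A disease score placed each animal between wild type (0) and Pompe vehicle (1). In each of 100 seeded draws, disease genes were picked by the difference between 2 vehicle and 2 wild-type libraries. The ends of the scale were set by another 2 of each, and the left-out vehicle and wild-type library and all treated libraries were scored. The treated libraries also entered the fit that picked the genes. There they added to the estimate of the spread but not to the difference, so picking and scoring were not fully separate. The score of an animal is its mean over draws. Groups were compared with 2-sided exact permutation tests, with Benjamini-Hochberg adjustment over 7 comparisons. With 5 against 5 the smallest p is 0.00794.

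Because every treatment was compared with the same Pompe vehicle libraries, overlaps with the disease comparison were set beside 40 simulated data sets in which all Pompe groups were unchanged, and beside 20 divisions of the vehicle libraries into separate sets for each comparison. A first version of that simulation held the observed vehicle counts fixed and so left out the shared-control term; it was replaced after its output was seen.

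Alternatives were RLE and upper-quartile scaling, no filter or a filter of 1 CPM in 5 libraries, DESeq2, limma-voom on unrounded counts, limma-trend on the deposited log2 CPM, RNA integrity number (RIN) or log2 RNA concentration as a covariate, only the compared groups in the fit, an adjusted p under 0.01, and each replicate left out in turn. For the score they were other rules for choosing genes, log2 CPM without TMM, the deposited log2 CPM and the cell type lists left out. Leaving out combination replicates 4 and 5, and replicate 3 of the vehicle and SRT groups, was added after seeing the data. No deposited file was left unused. Figures were drawn with matplotlib 3.10.9.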

Results

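Pompe disease is a lysosomal storage disease in which acid alpha-glucosidase, the enzyme that breaks down glycogen in lysosomes, is missing, and glycogen builds up in muscle. The gastrocnemius transcriptome was profiled in 25 mice: 5 wild-type mice on vehicle and 20 mice of the Pompe strain, 5 each on vehicle, ERT, SRT or both treatments. ERT supplies recombinant acid alpha-glucosidase (alglucosidase alfa), and SRT is an oral compound meant to lower glycogen synthesis. The design asks how Pompe muscle differs from wild-type muscle, what each treatment changes alone and together, and what difference from wild type is left. Library totals lay between 29669030 and 41296194 estimated counts, and 15335 genes were tested. RNA amounts differed between groups: the RNA concentration was 122 ± 55.1 ng per microlitre in the ERT group, 30.7 ± 18.4 in the combination group, 51.1 ± 29.3 in the SRT group, 54.6 ± 28.6 in the Pompe vehicle group and 26.9 ± 5.77 in the wild-type group (SD, n = 5 each).

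Gaa, the gene that encodes acid alpha-glucosidase (ENSMUSG00000025579, chromosome 11, 119267887 to 119285454, plus strand, GRCm38), was 18.1-fold lower in Pompe vehicle muscle than in wild-type muscle. It stood at 264 ± 24.5 CPM in wild-type animals and 14.6 ± 1.95 CPM in Pompe vehicle animals (SD, n = 5 each), a log2 fold change of -4.18 ± 0.11 (SE, adjusted p = 9.6e-20). The means were 14 ± 1.05 CPM with ERT, 14.7 ± 1.17 CPM with SRT and 17.2 ± 2.08 CPM with the combination (SD, n = 5 each), so all 20 Pompe libraries carried the transcript level of their label. Gys1, the muscle glycogen synthase (ENSMUSG00000003865, chromosome 7, 45434844 to 45456619), had 477 ± 30.7 CPM in wild-type and 431 ± 87.3 CPM in Pompe vehicle muscle (SD, n = 5 each), a difference that did not pass the test (adjusted p = 0.34). Gys1 stood at 408 ± 46.2 CPM with ERT, 452 ± 37.8 CPM with SRT and 535 ± 30.2 CPM with the combination (SD, n = 5 each), and none of these differed from Pompe vehicle (adjusted p = 0.92, 0.92 and 0.086). Pompe vehicle replicate 4 had 582 CPM of Gys1, the highest value of all 25 animals. Without it Gys1 was lower in Pompe vehicle than in wild type (log2 -0.28, adjusted p = 0.0208) and higher with the combination than with vehicle (log2 0.44, adjusted p = 0.00454).

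**Figure D1:**
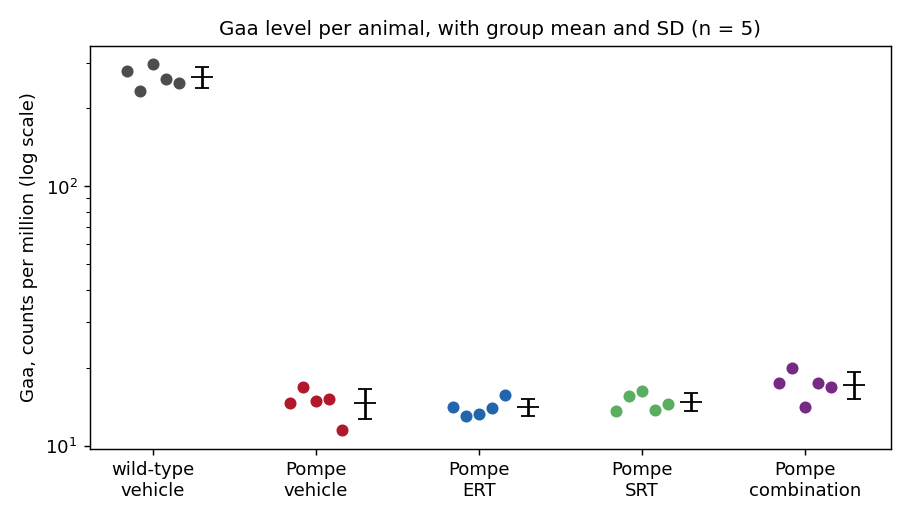
Gaa level of each animal in CPM on a log axis, by group, with the group mean and SD (n = 5). The 5 wild-type animals lie between 233 and 296 CPM and the 20 Pompe animals between 11.5 and 20 CPM.

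Untreated Pompe muscle carried a broad change: 2035 genes rose and 1669 fell against wild type, of which 822 and 250 changed at least 2-fold. The called genes were 24.2% of those tested. By the rule for named genes, the largest increases were in Mt3, a metallothionein that binds metal ions (131-fold, log2 7.03 ± 0.39 SE, adjusted p = 4.4e-11), Ccl22, a chemokine (log2 5.37 ± 0.8, adjusted p = 3.7e-05), and the metallothionein Mt2 (log2 4.99 ± 0.31, adjusted p = 2.2e-10). They were followed by Itgax, an integrin of myeloid cells (log2 4.71 ± 0.55), Mymk, the myoblast fusion protein myomaker (log2 4.7 ± 0.97), Retnlg (log2 4.68 ± 0.75), the ion channel Trpv3 (log2 4.58 ± 0.6) and Il1rn, the interleukin-1 receptor antagonist (log2 4.56 ± 0.81). Ccl22, Retnlg, Trpv3 and Il1rn had wild-type means of 0.0604, 0.0454, 0.0979 and 0.0589 CPM, about 3 counts or fewer, so the size of their increase is uncertain. Among the largest decreases besides Gaa were Odf3l2 (log2 -5.09 ± 1.01), Hal, which degrades histidine (log2 -3.8 ± 0.78), Kcnab1, a potassium channel subunit (log2 -3.53 ± 0.28), and Dkk3, a secreted glycoprotein (log2 -3.43 ± 0.31). Gvin1, a very large interferon-inducible GTPase, had no count in any Pompe vehicle library against 76 to 330 counts in wild-type libraries, so it was at least 76-fold lower. Gvin1 belongs to a multigene family whose reads can be shared, so its level is uncertain. Gvin1 and Hal stood at 5.79 and 7.99 CPM in 1 Pompe animal, combination replicate 5, beside 6.8 ± 2.85 and 6.08 ± 1.37 CPM in wild type (SD, n = 5).

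Many immune and lysosomal genes were among those that rose. Of 28 macrophage markers, 26 rose (27 adjusted over the list alone), among them Trem2 (log2 2.68 ± 0.29), a lipid-sensing receptor, Cd68, a lysosomal membrane protein of macrophages (log2 2.57 ± 0.28), and Mpeg1 (log2 3.01 ± 0.39). The macrophage list was called with the preset correlation (adjusted p = 2.69e-26) but not with an estimated correlation (adjusted p = 0.0995). Of 32 cytokines, chemokines and complement genes, 19 rose (22 adjusted over the list alone), including Il1b (log2 4.44 ± 0.7) and Ccl8 (log2 3.73 ± 0.56), with an adjusted p of 0.266 with an estimated correlation. Of 28 antigen presentation and interferon genes, 7 rose (7 adjusted over the list alone), led by the class II genes Cd74 (log2 2.11 ± 0.31) and H2-Ab1 (log2 2.19 ± 0.34), while the median of the list was -0.03 and its mean 0.44. Of 19 markers of other leukocytes, 4 rose (4 adjusted over the list alone), among them Retnlg and the T-cell gene Cd3d (log2 1.57 ± 0.46). The antigen presentation and other leukocyte lists were not called even with the preset correlation (adjusted p = 0.105 and 0.233). Of all genes tested, 24.2% were called. Of 45 lysosomal genes, 27 rose and none fell (29 and none adjusted over the list alone), among them Hexa, a beta-hexosaminidase subunit (log2 1.05 ± 0.1), Cd63 (log2 1.13 ± 0.12) and Galns (log2 1.28 ± 0.14); the list had an adjusted p of 0.0861 with an estimated correlation. Autophagy genes were mixed, with 6 higher and 8 lower of 38 (7 and 9 adjusted over the list alone). The autophagy receptor Sqstm1 rose (log2 0.92 ± 0.12) and Vmp1 fell (log2 -0.35 ± 0.08).

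Some genes of fibre damage, denervation and regeneration were higher as well. Muscle repair and sarcolemma damage was 1 of only 2 lists that held with an estimated correlation (adjusted p = 0.00194): 19 of its 27 genes rose and 1 fell (22 and 1 adjusted over the list alone), including the small heat shock protein Hspb7 (log2 1.59 ± 0.16), the annexin Anxa2 (log2 1.23 ± 0.15) and nestin, Nes (log2 1.62 ± 0.21). The other was oxidative stress and metallothionein (adjusted p = 0.0343 with an estimated correlation), with 9 higher and 5 lower of 26 (11 and 5 adjusted over the list alone); its increases included Mt1 (log2 3.12 ± 0.25) and Gpx1 (log2 1.18 ± 0.11). Of 23 denervation and neuromuscular junction genes, 10 rose and none fell (the same adjusted over the list alone), among them Runx1 (log2 2.41 ± 0.22), Ncam1 (log2 2 ± 0.2) and the acetylcholine receptor subunit Chrnd (log2 2.86 ± 0.32), with an adjusted p of 0.0995 with an estimated correlation. Of 20 regeneration genes, 9 rose and 1 fell (the same adjusted over the list alone), with increases in embryonic myosin Myh3 (log2 3.03 ± 0.56) and the calcium pump regulator Sln (log2 3.27 ± 0.47). That list had an adjusted p of 0.297 with an estimated correlation. Of 36 extracellular matrix genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone), led by the protease inhibitor Timp1 (log2 4.43 ± 0.46). Of 24 cell cycle genes, 8 rose (9 adjusted over the list alone), among them Mki67 (log2 1.97 ± 0.34). These last 2 lists had adjusted p of 0.675 and 0.448 with an estimated correlation.

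Many genes of oxidative metabolism were lower in Pompe vehicle muscle. Of 44 oxidative phosphorylation and TCA cycle genes, 27 fell and none rose (32 and none adjusted over the list alone), including Suclg1 (log2 -0.56 ± 0.09) and citrate synthase, Cs (log2 -0.55 ± 0.1). Of 35 fatty acid oxidation genes, 17 fell and 1 rose (23 and 1 adjusted over the list alone): Etfdh and Acsl1 fell (log2 -0.69 ± 0.16 and -0.68 ± 0.16) and Ucp2 rose (log2 1.06 ± 0.19). Both lists had an adjusted p of 0.448 with an estimated correlation. Of 12 mitochondrially encoded genes, a list kept as a technical measure, 4 fell and none rose (6 and none adjusted over the list alone; adjusted p = 0.645 with an estimated correlation), and they held 14.6 ± 2.2% of the counts with vehicle and 17.3 ± 1% in wild type (SD, n = 5 each). Among 41 genes of glycolysis and glucose uptake, 12 fell and 4 rose (the same adjusted over the list alone; adjusted p = 0.495 with an estimated correlation). The insulin-responsive glucose transporter Slc2a4 fell (log2 -0.56 ± 0.13) while the transporter Slc2a1 rose (log2 1.47 ± 0.27). Among 28 genes of glycogen metabolism, 5 fell and 2 rose (the same adjusted over the list alone): the branching enzyme Gbe1 and the glycogen-binding protein Stbd1 rose (log2 0.94 ± 0.14 and 0.86 ± 0.16), and the phosphatase subunit Ppp1r3e fell (log2 -1.78 ± 0.27). The glycogen list was not called even with the preset correlation (adjusted p = 0.182). Glycogen phosphorylase, Pygm, was not called (log2 -0.4 ± 0.16, adjusted p = 0.072), though it was without vehicle replicate 4 (adjusted p = 0.0375). Of the 15335 genes, 5481 had an unadjusted p under 0.05, where 767 would be expected by chance.

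ERT alone left no gene past the threshold against Pompe vehicle with edgeR. The smallest adjusted p was 0.52, 994 genes had an unadjusted p under 0.05 against 767 expected by chance, DESeq2 called 5 genes and limma-voom called 0. Cd68 stood at 18.3 ± 6.4 CPM with ERT and 20.5 ± 5.68 CPM with vehicle, Myh3 at 16.3 ± 11.8 and 20.1 ± 7.23 CPM, and Mt3 at 138 ± 55.4 and 163 ± 45.7 CPM (SD, n = 5 each). With the preset correlation 10 lists were called, such as fatty acid oxidation (median log2 0.23) and heat shock chaperones (median log2 0.15), yet no member of either list was called, also not adjusted over the list alone, and both had an adjusted p of 0.896 with an estimated correlation. Animals on ERT spread widely, and Myh3 ran from 3.86 to 35.2 CPM among them.

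SRT alone called 8 genes against Pompe vehicle, 2 higher and 6 lower. Npy1r, a neuropeptide Y receptor, rose from 2.49 ± 0.441 to 5.27 ± 0.938 CPM against 5.81 ± 1.31 CPM in wild type (SD, n = 5 each; log2 1.08 ± 0.19, adjusted p = 0.047), and Tmem204, a membrane protein of endothelial cells, rose as well (log2 0.75 ± 0.14). Sord, which makes fructose from sorbitol, fell from 105 ± 18.2 to 68 ± 7.08 CPM against 82.9 ± 5.9 CPM in wild type (log2 -0.63 ± 0.1, adjusted p = 0.014; SD, n = 5 each). Reep6 (log2 -0.95 ± 0.18), Pygo1 (log2 -0.61 ± 0.11), the arginine sensor Castor2 (log2 -0.51 ± 0.1) and the scaffold protein Mpp6 (log2 -0.38 ± 0.07) were the other named genes that fell. The remaining call, Stard10 (log2 -0.50 ± 0.10), is named because the count is small and was chosen after its values were seen. An unadjusted p under 0.05 was found for 1267 genes, limma-voom called 1 gene and DESeq2 called 53. The count was small enough to depend on single animals: it was 1 without vehicle replicate 1, 2 or 4, 2 without vehicle replicate 3, 0 without vehicle replicate 5, 1 without SRT replicate 1, 2 without SRT replicate 2 or 5, 0 without SRT replicate 4 and 10 without SRT replicate 3. Sord kept its call in most of these fits, failing without vehicle replicate 5 (adjusted p = 0.0607) and SRT replicate 4 (adjusted p = 0.0604). The other named genes each lost theirs without most of these 10 libraries, with adjusted p up to 0.212 for Castor2. With the preset correlation 11 lists were called, among them extracellular matrix (median log2 0.30) and mitochondrially encoded genes (median log2 -0.24), with no member called over all genes. Both had an adjusted p of 0.809 with an estimated correlation.

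The combination of ERT and SRT changed 730 genes against Pompe vehicle (4.8% of those tested), 340 higher and 390 lower, with 46 and 71 changed at least 2-fold. By the part of the rule for named genes that requires groups without overlap, the largest increase was in Odf3l2 (log2 4.01 ± 0.99, adjusted p = 0.025). Ttc25, a component of motile cilia (log2 3.18 ± 0.46, adjusted p = 0.00054), and Aqp4, the water channel of fast fibres, came next. Aqp4 went from 4.53 ± 2.2 to 21.8 ± 5.8 CPM against 32.4 ± 6.53 CPM in wild type (SD, n = 5 each, log2 2.26 ± 0.37, adjusted p = 0.0018). Car9, a carbonic anhydrase, Rbp7, a retinol-binding protein, the glutamate transporter Slc1a1 and Ntsr2 rose by log2 1.45 to 1.94. Odf3l2 was not called without vehicle replicate 2, 3 or 5 or combination replicate 5 (adjusted p = 0.0668, 0.073, 0.0565 and 0.0553). By the same part of the rule the largest decrease was in Fbxl22, an F-box protein of the Z-disc (log2 -1.85 ± 0.27, adjusted p = 0.00065). Its level went from 12.9 ± 3.65 to 3.56 ± 0.356 CPM against 3.06 ± 0.674 CPM in wild type (SD, n = 5 each). C1ql3 (log2 -1.81 ± 0.32) and the protease inhibitor Serpinb1a (log2 -1.6 ± 0.29) came next. Ccl5 and Cxcl10, which that part left out, fell more (log2 -2.44 and -1.93, adjusted p = 0.0384 and 0.0489). They lost their calls in 12 of 21 and 18 of 22 alternatives. Mt3 fell to 54.1 ± 16 CPM (log2 -1.59 ± 0.29), still far above the 1.21 ± 0.635 CPM of wild type (SD, n = 5 each). Apobec1 and Serpinb6b fell by log2 -1.46 and -1.39. Ttc25 had 0.773 ± 0.27 CPM in wild type and 6.88 ± 3.71 CPM with the combination, so its level moved away from that of wild type.

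Several groups that were high in Pompe muscle had members that fell with the combination. Of 45 lysosomal genes, 3 fell (6 adjusted over the list alone), among them Hexa, from 106 ± 13.1 to 72.7 ± 3.38 CPM (SD, n = 5 each; log2 -0.55 ± 0.1), and Cd63 (log2 -0.43 ± 0.12). Hexa kept its call with any single library left out, while Cd63 lost its call without vehicle replicate 1, 2, 3 or 5 or combination replicate 2, 3, 4 or 5 (adjusted p from 0.0516 to 0.103). Of 28 macrophage markers, 2 fell, Trem2 (log2 -1.15 ± 0.27) and Lgmn (log2 -0.6 ± 0.15), and 12 fell adjusted over the list alone. Neither was called without vehicle replicate 2 (adjusted p = 0.0509 for both), and Lgmn also not without vehicle replicate 3 or 5 or combination replicate 4 (adjusted p = 0.06, 0.0566 and 0.0587). Cd68 was not called (log2 -0.54 ± 0.25, adjusted p = 0.22). Of 27 muscle repair genes, 7 fell (8 adjusted over the list alone), including the annexin Anxa6 (log2 -0.42 ± 0.08). Of 23 denervation genes, 4 fell (6 lower and 1 higher adjusted over the list alone), among them Ncam1, from 29.1 ± 6.82 to 13 ± 2.84 CPM (SD, n = 5 each; log2 -1.16 ± 0.2). Embryonic myosin Myh3 was not called (log2 -1.75 ± 0.52, adjusted p = 0.057), though it was without combination replicate 1 or 3 (adjusted p = 0.0443 and 0.0398). The lysosome, macrophage and denervation lists had an adjusted p of 0.489 with an estimated correlation, and muscle repair had 0.178. Among 32 lipogenesis and cholesterol genes, 6 fell and 1 rose (9 and 3 adjusted over the list alone). Sesn3, a sestrin that restrains mTORC1, fell to 13.9 ± 1.44 CPM against 21 ± 1.12 CPM with vehicle and 16.5 ± 1.44 CPM in wild type (SD, n = 5 each; log2 -0.59 ± 0.07, adjusted p = 0.00032), and it was lower than in wild type as well (adjusted p = 0.0313).

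Some genes of the glycolysis, endothelial and chaperone lists were called with the combination, and 1 of the oxidative phosphorylation list, beside 4.8% of all genes tested. Among 41 genes of glycolysis and glucose uptake, 4 rose and 1 fell (9 and 2 adjusted over the list alone): Slc2a4 rose (log2 0.66 ± 0.13), as did Pfkfb1, which controls glycolytic flux (log2 0.83 ± 0.17), and Slc2a1 fell (log2 -1.11 ± 0.26). The list had an adjusted p of 0.315 with an estimated correlation. Of 44 oxidative phosphorylation genes only Suclg1 was called (log2 0.35 ± 0.09; 3 adjusted over the list alone), and not without vehicle replicate 2 or 3 or combination replicate 2 or 4 (adjusted p = 0.0844, 0.0905, 0.0609 and 0.0557). Of 15 endothelial markers, 4 rose (5 adjusted over the list alone), including the water channel Aqp1 (log2 0.8 ± 0.16). The oxidative phosphorylation, endothelial and chaperone lists each had an adjusted p of 0.489 with an estimated correlation. Of 21 chaperones, 3 rose (5 adjusted over the list alone), but the values of Hspa1a and Hspa1b came from few animals: Hspa1b stood at 56.6 ± 90.4 CPM (SD, n = 5), with a range from 4.44 to 215 CPM. Without combination replicate 2 neither was called (adjusted p = 0.2 and 0.305), nor was either without vehicle replicate 1, 2, 3 or 5 (adjusted p from 0.0666 to 0.109).

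An unadjusted p under 0.05 was found for 3140 genes in this comparison. The count of 730 depended on single animals: it was 425 without vehicle replicate 1, 297 without vehicle replicate 2 and 274 without vehicle replicate 3, and between 500 and 973 without any other animal of these groups. It was 79 when only these groups entered the fit, 450 and 315 with RIN and RNA concentration as covariates, 1191 with DESeq2 and 152 at an adjusted p under 0.01. Combination replicates 4 and 5 stood apart from the other libraries in mapped share (90.4% and 90.2% against at most 89.4%), and without both the count was 663, of which 352 genes were among the 730.

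**Figure D2:**
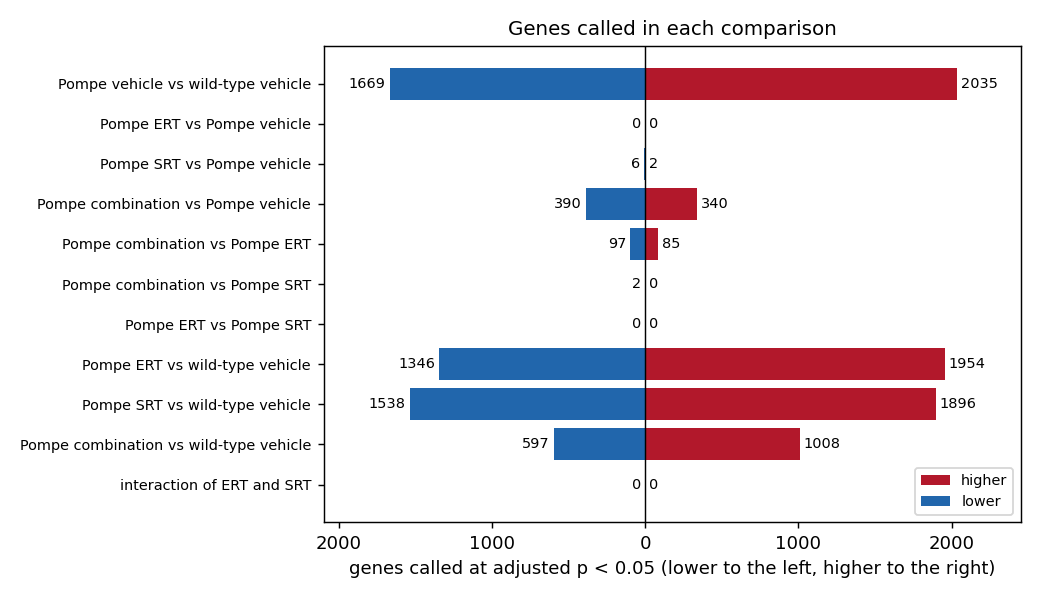
Number of genes called at an adjusted p under 0.05 in each comparison, lower genes to the left and higher genes to the right of 0. The disease comparison has 2035 higher and 1669 lower genes, ERT alone 0 and 0, SRT alone 2 and 6, and the combination 340 and 390 against Pompe vehicle.

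Set on the scale from wild type to Pompe vehicle, the combination group had the mean nearest to wild type among the Pompe groups. Its animals (0.423 to 0.821) overlapped with those on ERT (0.642 to 1.138) and on vehicle (0.779 to 1.109). The disease score was 0.999 ± 0.135 in Pompe vehicle, 0.938 ± 0.195 with ERT, 0.944 ± 0.084 with SRT, 0.644 ± 0.154 with the combination and -0.009 ± 0.061 in wild type (SD, n = 5 each). The combination score was below that of vehicle (difference -0.355, exact permutation p = 0.0159, adjusted p = 0.037) and of SRT (difference -0.3, exact p = 0.00794, adjusted p = 0.0278), and it was above wild type (difference 0.653, exact p = 0.00794, adjusted p = 0.0278). Its difference from ERT did not hold after adjustment (-0.294, exact p = 0.0397, adjusted p = 0.0694). Scores with ERT and SRT alone did not differ from vehicle (exact permutation adjusted p = 0.667 and 0.622), nor from each other (exact permutation adjusted p = 0.952). The 5 combination animals scored 0.821, 0.652, 0.746, 0.579 and 0.423, and without replicates 4 and 5 the mean of the other 3 was 0.739 ± 0.085 (SD, n = 3; exact permutation p = 0.0536 against vehicle, where 0.0179 is the smallest p possible).

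**Figure D3:**
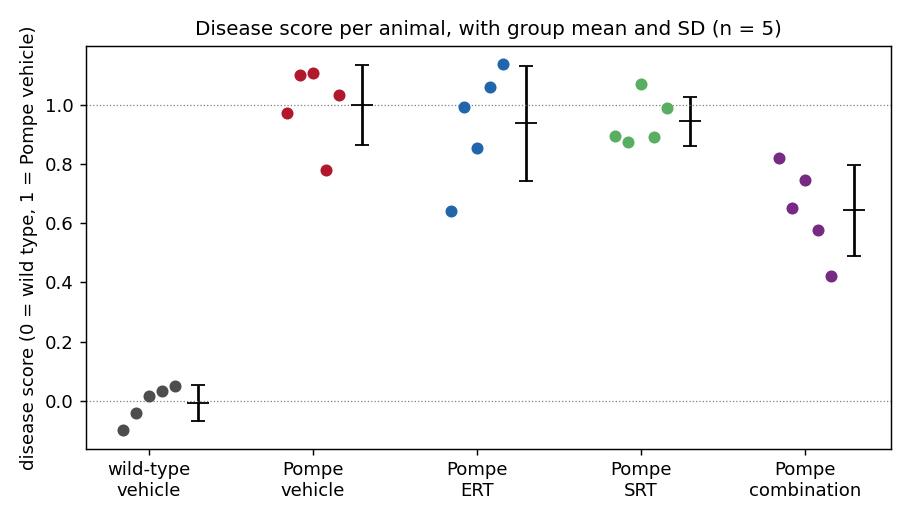
Disease score of each animal, from 0 (wild type) to 1 (Pompe vehicle), by group, with the group mean and SD (n = 5). Combination animals lie between 0.423 and 0.821, SRT animals between 0.875 and 1.07, ERT animals between 0.642 and 1.138 and Pompe vehicle animals between 0.779 and 1.109.

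Genes called in both the disease and the combination comparison nearly all moved in opposite directions: 534 of 536, against 88.8 for independent lists. With separate vehicle libraries for each comparison the median was 90.5 opposite calls over 20 divisions (range 7 to 279), among a median of 91 genes called in both. This also leaves each comparison fewer vehicle animals, so the drop cannot be put down to the sharing. Over the 3704 disease genes, 90.8% had the opposite sign with the combination, 70.7% with ERT and 68.5% with SRT. In 40 simulated data sets without any treatment effect the means were 62.2%, 61.9% and 61.9%, with maxima of 63.5%, 63.3% and 63.9%. Separate vehicle libraries gave medians of 84.6% (range 75.3% to 89.6%), 59.7% (42.4% to 73.9%) and 58.3% (39.5% to 73%). The ranges for ERT and SRT were wide and held the observed shares. The covariance of the disease and combination log2 fold changes was -0.178, beside -0.0453 in the simulations. It was -0.0498 for ERT and -0.0712 for SRT, beside -0.0455 in each simulation. SRT called 8 genes, of which 5 were disease genes, all in the opposite direction, against 1 for independent lists. With separate vehicle libraries the median for SRT was 0 (at most 1). Leaving out vehicle replicate 1, 2 or 3 brought the 534 down to 327, 225 or 210.

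**Figure D4:**
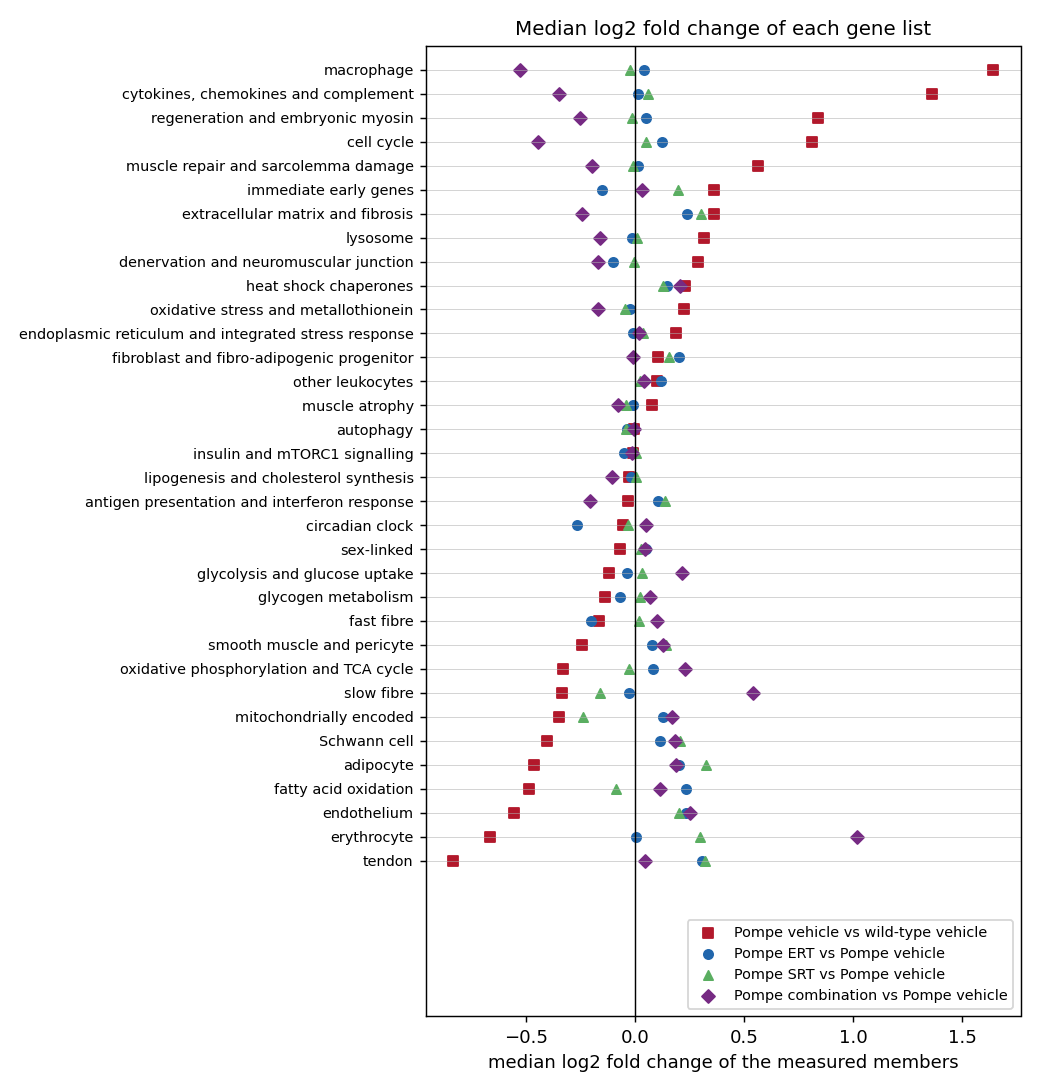
Median log2 fold change of the measured members of each of 34 gene lists, for the disease comparison (squares) and for ERT (circles), SRT (triangles) and the combination (diamonds) against Pompe vehicle. Macrophage markers have a median of 1.64 in the disease comparison and -0.53 with the combination.

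Against ERT alone, the combination changed 182 genes, 85 higher and 97 lower. Nsun2, an RNA methyltransferase (log2 0.71 ± 0.11), the transcription factor Atoh8 (log2 1 ± 0.16) and Ttc25 (log2 2.69 ± 0.45) were among the higher ones. Sesn3 (log2 -0.53 ± 0.07, adjusted p = 0.0026), St6galnac4 (log2 -0.59 ± 0.09) and the fatty acid desaturase Fads1 (log2 -0.65 ± 0.11) were among the lower ones. This count moved by over 1.5 times with every library left out: to 585, 36, 49, 56 and 39 without ERT replicates 1 to 5 and to 430, 280, 452, 58 and 44 without combination replicates 1 to 5. It was 0 with RNA concentration as a covariate. Against SRT alone, edgeR called 2 genes, Fam171b (log2 -1.51 ± 0.24) and the transcription factor Trp63 (log2 -0.83 ± 0.14), both lower with the combination (adjusted p = 0.022), while 2283 genes had an unadjusted p under 0.05, limma-voom called 2 and DESeq2 called 208. That count was 7, 8, 0, 0 and 1 without SRT replicates 1 to 5, and 28, 0, 1, 2 and 6 without combination replicates 1 to 5. ERT and SRT alone did not separate: edgeR called 0 genes, with 972 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 5. The departure from additive effects of ERT and SRT also gave 0 genes with edgeR (smallest adjusted p 0.17), with 1544 at an unadjusted p under 0.05 0 by limma-voom and 11 by DESeq2, and it was 2 without vehicle replicate 3, 7 without ERT replicate 1 and 2 without combination replicate 3.

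All treated Pompe groups still differed from wild type. ERT left 1954 genes higher and 1346 lower than wild type, SRT left 1896 and 1538, and the combination left 1008 and 597. Map1a, a microtubule-associated protein, stood at 19.3 ± 2.76 CPM in wild type and at 214 ± 36.3, 176 ± 40, 145 ± 22.3 and 99.1 ± 20.4 CPM with vehicle, ERT, SRT and the combination (SD, n = 5 each). Mt3, the motor protein gene Myo5a (log2 1.81, 1.68 and 1.47) and Prune2 (log2 3.34, 3.06 and 2.65) were higher than wild type with ERT, SRT and the combination. Gaa, Exoc7, part of the exocyst (log2 -1.02, -0.88 and -0.92), Kcnab1 (log2 -2.93, -3.47 and -2.29) and Dkk3 (log2 -3.23, -3.24 and -3.59) were lower in all 3. The 1605 calls of the combination were 854 when only these groups entered the fit, and the 3300 calls with ERT were 806 with RNA concentration as a covariate, fewer than the 1660 of the combination in that fit.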

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

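The tests on wild-type tissue under a combination label and all tests on combination replicate 5 were chosen after the values were seen; the tests on RNA integrity and RNA concentration were planned before.

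In 18 measures tested in 5 groups, 7 values from 6 animals lay far from those of the other 4 animals of their group, where chance gives about 1 in 20 groups, or 4.5 of the 90. RIN was 7.3 in ERT replicate 5 (8.1 to 8.4 in the others) and 6.5 in combination replicate 4 (7.6 to 7.7). RNA concentration was 102 ng per microlitre in SRT replicate 5 (27.9 to 47). Haemoglobin genes took 0.0937% of counts in SRT replicate 2 (0.0407 to 0.0479) and 0.0568% in combination replicate 5 (0.0911 to 0.0967). Gys1, the muscle glycogen synthase, stood at 582.2 CPM in vehicle replicate 4 (370.5 to 430.2). Lamp1, a lysosomal membrane protein, stood at 610.2 CPM in combination replicate 5 (483.1 to 517.9).

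Combination animals scored nearer to wild type than vehicle animals on average, by -0.355. Among the 15 animals on vehicle, ERT or SRT the trend of the score with RNA integrity predicts a shift of 0.025 (95% interval -0.09 to 0.14), and that with RNA concentration -0.055 (-0.122 to 0.012). Neither trend, as measured in those animals, accounts for it alone. Combination replicates 1 to 5 had 58.4, 16.9, 39.5, 25 and 13.6 ng per microlitre of RNA and scores of 0.821, 0.652, 0.746, 0.579 and 0.423. A steeper trend with RNA concentration within that group was not tested. Wild-type tissue under a combination label would need 93.9 CPM of Gaa at the group's mean score, and the highest value was 20 CPM. Replicates 4 and 5, which had the lowest scores, carry part of the shift: without both the difference was -0.26 (exact permutation p = 0.0536). An unrecorded batch stays open because the labels give none, so an effect of treatment with both may explain the shift only as a hypothesis. Library numbers in the labels run group by group. Any effect that follows this order cannot be told apart from group in any comparison, the disease comparison included.

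Combination replicate 5, the only animal with a later birth date per the labels, stood near or past wild-type level for some genes that separate wild-type from Pompe animals. Of 78 genes whose wild-type libraries lie over 1 log2 unit from all vehicle, ERT and SRT libraries, 15 lay at least 0.8 of the way from Pompe to wild type, or past wild type, in this animal, among them Gvin1, Hal, Trim12a and Wnt4, against 0, 1, 0 and 1 in the other combination animals. It differed from every other Pompe animal by over 2 log2 units at 18 genes, where the highest other animal had 6. Of the 15 genes, 4 pairs lay within 5 Mb of each other (0.78 in random draws from the 78 genes, permutation p = 0.018). They were the pairs among Trim12a, Trim30d and Gvin1 on chromosome 7, and Pik3r5 with Trpv3 on chromosome 11. Most pairs thus came from a single locus whose counts are uncertain, so a strain background that differs in this animal is only a candidate explanation. An effect of treatment with both that is shared by the group is argued against for the 9 genes lower in Pompe muscle. There the other 4 animals had a median position of 0 on the scale to wild type. The genes were picked by the levels of replicate 5, so a stronger response of this animal alone cannot be excluded. For the 6 genes higher in Pompe muscle (median 0.36) treatment and background cannot be told apart, since the other 4 animals had moved as well. Gaa was 6.4% of the wild-type mean, which excludes wild-type tissue, and counts of Gvin1 and the Trim genes are uncertain because of related genes.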

How the results depend on the processing

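Leaving out combination replicates 4 and 5 together, and replicate 3 of the vehicle and SRT groups together, were tests chosen after seeing the data; the other settings were planned. The causes of the changes below were not tested, except where the construction of a setting shows them.

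The log2 fold change of Gaa stayed between -4.24 and -4.10 with each replicate left out, and the disease count between 3124 and 3799. The disease count was 3098 with RNA concentration as a covariate and 4035 with DESeq2, and it moved to 2168 at an adjusted p under 0.01. Of 127 named genes called in the disease comparison, 111 were called with the same sign in every alternative. For the combination that number was 17 of 65, among them Ttc25, Aqp4, Mt3, Hexa and Ncam1. No named gene called with SRT (7), with the combination against ERT (10) or against SRT (2) was called in every alternative. All 10 named genes of each comparison of a treated group with wild type were, and no named gene that was called changed sign in any alternative.

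The treatment counts moved most. Without single replicates they ran from 0 to 10 for SRT, from 274 to 973 for the combination, from 36 to 585 for the combination against ERT and from 0 to 28 against SRT, and from 0 to 7 for the departure from additive effects. Against wild type they ran from 2530 to 3718 with ERT, from 2730 to 3347 with SRT and from 1193 to 2098 with the combination, which had its highest count without combination replicate 5. They were 0 throughout for ERT, and for ERT against SRT. The combination score stayed between 0.645 and 0.676 with other rules for choosing genes, other values or without cell type lists (exact permutation p of 0.0159 or 0.0238 against vehicle). Without single replicates it ran from 0.6 to 0.699, that of ERT from 0.888 to 1.012 and that of SRT from 0.913 to 0.962. Opposite calls ran from 210 to 728.

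An adjusted p under 0.01, a stricter threshold, left 2168 disease genes, 0 with SRT, 152 with the combination (112 of them disease genes in the opposite direction), 16 against ERT and 0 against SRT, and 1784, 2008 and 664 against wild type with ERT, SRT and the combination. DESeq2, which made more false calls in simulated data, called 5 genes with ERT, 53 with SRT, 1191 with the combination, 720 and 208 for the combination against ERT and SRT, 5 for ERT against SRT and 11 for the departure from additive effects. Limma-voom called 1 gene with SRT. The deposited log2 values gave 2 with SRT, and 110 and 7 for the combination against ERT and SRT. A filter of 1 CPM gave 14 with SRT.

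With RIN as a covariate SRT had 15 calls, the combination 450, and the combination against ERT and SRT 6 and 0. With RNA concentration the combination had 315, and 0 and 0 against ERT and SRT, ERT against SRT had 1, and ERT against wild type had 806, below the 1660 of the combination. RNA concentration differs between groups, so this covariate also removes part of the group differences by construction. With only the compared groups in the fit, which leaves fewer libraries to estimate the spread, the combination had 79 calls, 0 and 0 against ERT and SRT, and 854 against wild type, and ERT against SRT had 1. Without combination replicates 4 and 5, the combination had 15 calls against ERT and its score was 0.739. Without replicate 3 of the vehicle and SRT groups, SRT had 2 calls, the combination 261, and 0 against SRT. With separate vehicle libraries for both comparisons, and so fewer vehicle animals in each, the median number of opposite calls was 90.5.

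Gene lists called in the disease comparison numbered 17 with the preset and 2 with an estimated correlation. Of these 17, fry did not call extracellular matrix (fry adjusted p = 0.109), immediate early genes (0.104) or mitochondrially encoded genes (0.0611). It called all the others, among them macrophage (3.4e-05) and lysosome (1.02e-06), and muscle atrophy as well (3.71e-05). With an estimated correlation 0 lists were called with ERT, 0 with SRT, 0 with the combination, 0 and 0 for the combination against ERT and SRT, and 0 for the departure from additive effects. Fry called 0 with ERT, 0 with SRT, 5 with the combination, 6 and 7 for the combination against ERT and SRT, and 0 for the departure. With the preset correlation these were 10, 11, 17, 17, 19 and 21. Without single replicates the counts ran from 15 to 19 for disease, 7 to 12 for ERT, 9 to 13 for SRT, 14 to 19 for the combination, 16 to 20 against ERT, 19 to 22 against SRT and 18 to 23 for the departure.

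The direction of the disease calls followed the scaling. With edgeR 2035 genes were higher and 1669 lower (54.9% higher). The deposited log2 values gave 1601 higher and 2136 lower (42.8%). Each deposited column is its library's log2 CPM times a fixed factor, and with every column divided by its factor the split was 2023 higher and 1706 lower (54.3%), so the factor made the difference. Limma-voom gave 52.5% and upper-quartile scaling 60.9%.

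One count was worth at most 0.0337 CPM, so depth limits the fold changes of genes near 0 in a group, such as Il1rn and Trpv3 in wild type (0.0589 and 0.0979 CPM) and Gvin1, which had no count with vehicle. No paired analysis was possible because each library came from a different animal.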

Other observations

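The test of the genes next to Gaa and the counts over other divisions of the animals were planned; leaving the Cd300 genes out of the former was a test chosen after its result was seen.

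Many endothelial genes were lower in Pompe vehicle muscle, and some rose with the combination. Against vehicle, the list median moved about as far with ERT and SRT (log2 0.234 and 0.204) as with the combination (log2 0.254). No member was called with ERT or SRT alone. Of 15 endothelial markers, 10 fell in Pompe vehicle muscle (11 adjusted over the list alone), among them Esam, an adhesion molecule of endothelial junctions (log2 -0.61 ± 0.12), and Emcn (log2 -0.77 ± 0.18), and the list had an adjusted p of 0.448 with an estimated correlation. With the combination, where the list had an adjusted p of 0.489 with an estimated correlation, Aqp1 rose and kept its call with any single library left out. Flt1, a receptor for vascular growth factor, rose too (log2 0.59 ± 0.16), but was not called without vehicle replicate 1, 2, 3 or 5 (adjusted p = 0.0683, 0.0742, 0.0835 and 0.0592) or combination replicate 2 or 3 (adjusted p = 0.0816 and 0.0599). Of 7 erythrocyte genes, 4 rose with the combination (6 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation), such as the beta-globin gene Hbb-bt, which stood at 44.9 ± 20 CPM with vehicle, 97.6 ± 15.8 CPM with the combination and 77 ± 8.68 CPM in wild type (SD, n = 5 each). Hbb-bt was not called with the combination without vehicle replicate 1, 2 or 3 (adjusted p = 0.0518, 0.0635 and 0.073). In the disease comparison 2 of the 7 erythrocyte genes fell (4 adjusted over the list alone; adjusted p = 0.491 with an estimated correlation), Hbb-bt and Hba-a1, each near the threshold (adjusted p = 0.0401 and 0.0481) and not called in 11 and 14 of 21 alternatives. Hbb-bt was not called without vehicle replicate 1, 2 or 3 (adjusted p = 0.0992, 0.091 and 0.101) or wild-type replicate 1, 2, 4 or 5 (adjusted p = 0.0638, 0.0845, 0.0579 and 0.069), and Hba-a1 not without vehicle replicate 1, 2 or 3 (adjusted p = 0.108, 0.0956 and 0.118) or any wild-type replicate from 1 to 5 (adjusted p = 0.078, 0.0954, 0.0502, 0.0707 and 0.0772). Globin genes share sequence, so the split of reads among them is uncertain, and they measure blood left in the tissue as well as cells.

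Some tendon genes were lower in Pompe vehicle muscle. Of 12, 6 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.448 with an estimated correlation). The collagen-binding proteoglycans Fmod and Kera were among those that fell (log2 -1.36 ± 0.26 and -1.45 ± 0.3). No tendon gene was called with any treatment against vehicle. Of 19 clock genes, 4 fell and 1 rose in Pompe vehicle muscle (the same adjusted over the list alone; adjusted p = 0.675 with an estimated correlation): Hlf, Nr1d1, Per1 and Cry1 were lower (log2 -1.72 ± 0.34, -0.55 ± 0.14, -1.36 ± 0.45 and -0.37 ± 0.13) and Bhlhe41 higher (log2 0.5 ± 0.15). The clock list was not called with the preset correlation either (adjusted p = 0.294). Per1 was not called without vehicle replicate 1, 2 or 5 (adjusted p = 0.0707, 0.0645 and 0.0507) or wild-type replicate 1, 2 or 4 (adjusted p = 0.0802, 0.0748 and 0.0517), and Cry1 was not tested with single animals left out in this comparison. Of 24 immediate early genes, 6 rose (6 adjusted over the list alone), led by Egr3 (log2 3.77 ± 0.86), with an adjusted p of 0.675 with an estimated correlation.

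Sord and Npy1r, picked from the 8 genes called with SRT, stood at similar levels with SRT and with the combination. Sord stood at 68 ± 7.08 CPM with SRT and 68.2 ± 4.02 CPM with the combination, against 105 ± 18.2 CPM with vehicle and 97.7 ± 9.59 CPM with ERT (SD, n = 5 each). Npy1r stood at 5.27 ± 0.938 and 5.33 ± 1.44 CPM with SRT and the combination, against 2.49 ± 0.441 and 3.26 ± 0.604 CPM with vehicle and ERT (SD, n = 5 each). For the combination against ERT, 7 of the 8 genes were not called, Npy1r among them (adjusted p = 0.0577), and the call of Sord was not tested with single animals left out. The comparisons with vehicle share the vehicle libraries, and simulations without any effect gave covariances of 0.0458 between the combination and each single treatment, beside 0.0604 observed for SRT and 0.0409 for ERT. The correlations were 0.496 for SRT and 0.349 for ERT, beside 0.493 and 0.497 in the simulations. Effects of the combination add variance that lowers a correlation, so whether the treatments are alike beyond their shared controls stays open.

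Disease calls were denser near Gaa on chromosome 11. Within 10 Mb of Gaa 67 of 194 genes were called (34.5%) against 24% elsewhere, an odds ratio of 1.67 (95% interval 1.22 to 2.27, Fisher's exact p = 0.00126), and 2% of 14579 windows of the genome had as high a share. Among these genes is Exoc7, lower than wild type in every treated group. Without 7 Cd300 genes, related receptors of myeloid cells that share reads, the odds ratio was 1.53 (1.11 to 2.1, Fisher's exact p = 0.00764), and for changes of at least 2-fold it was 1.45 (0.851 to 2.35, Fisher's exact p = 0.12). Chromosome segments from another strain that flank the changed Gaa allele may therefore account for some disease calls, a hypothesis that needs genotypes.

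Each comparison was repeated over 100 divisions of its animals, the real division included. No other division reached the disease calls (3704, highest other 891), those of the combination (730, highest other 455) or its opposite calls (534, highest other 352). Opposite calls add no separate support, since other divisions called a median of 0 genes with the combination. Against wild type none reached the counts of ERT (3300, highest other 1144), SRT (3434, highest other 3) or the combination (1605, highest other 772). For SRT against vehicle only the real division reached the 8 genes (highest other 3). That count ran from 0 to 10 without single replicates. A share of 1 in 100 is the smallest these divisions can give and was not adjusted for the number of counts tested. Chance is therefore argued against for these counts, but not excluded. For the combination against SRT (2 genes) 2 of the 100 divisions reached the count, and the other of them called more genes (3). With RIN or RNA concentration as a covariate the real count was 0. For the combination against ERT 4 divisions reached the 182 genes, and the highest other division called 864, which points to a structure of these samples. These shares of divisions were not adjusted for the number of counts tested, so chance is not firmly excluded for either comparison. With RIN or RNA concentration, which the labels give, as a covariate the real count against ERT was 6 or 0. Chance is not excluded where edgeR called 0 genes, which all 100 divisions reach: ERT (highest other 1), ERT against SRT (highest other 1) and the departure from additive effects (highest other 12).

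Numbers of lists called with the preset correlation mean less. Chance is not excluded for the disease comparison (17 lists, highest other 21, reached by 18 divisions), ERT (10 lists, highest other 22, reached by 55), SRT (11, highest other 18, reached by 27), the combination (17, highest other 23, reached by 10), or the combination against ERT (17, highest other 23, reached by 23) or SRT (19, highest other 23, reached by 7). For the departure from additive effects 2 divisions reached the 21 lists, the real one and another with as many. This share was not adjusted for the number of counts tested, so chance is not firmly excluded there. No list of that comparison held with an estimated correlation or with fry.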
